A study of Rattus norvegicus with 12 samples.

How the data were processed

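Total RNA was measured by sequencing in cardiomyocytes (heart muscle cells) isolated from Sprague-Dawley rats 1 to 3 days old. Per the labels, cells were plated at 40000 per cm2 on coated dishes and kept for 24 h in medium with 7% serum. AraC (cytosine arabinoside, which stops dividing cells) was present at 10 µM over the first days and was withdrawn 24 h before treatment. The cells then received vehicle (acetic acid), endothelin-1 (ET-1, 100 nM) or phenylephrine (PE, an alpha-1 adrenergic agonist, 10 µM) for 24 h. Each was combined with DMSO or with JQ1 at 1 µM, a compound that blocks the bromodomains of the BET proteins. These 6 groups held 2 libraries each, 12 in all, named replicate 1 and replicate 2. The labels do not say that the replicates were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

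RNA was purified on columns with DNase treatment, and ribosomal RNA was removed before stranded libraries were made, per the labels. Trim Galore 0.6.0, STAR 2.7.1a, StringTie 1.3.4d and DESeq2 1.24.0 are listed per the submitters' processing notes, with the rat genome build rn6 (Rnor_6.0). The deposited tables gave each transcript's mean coverage (signal) per base and its FPKM, per the file headers. The authors' FPKM values had been normalized for transcript length and for each library's total. Each table listed 41078 transcripts of 32883 genes with symbols, identifiers and coordinates, which are quoted here as deposited on rn6. Sequences of the genome and its annotation of exons and untranslated parts were not used here. Strand settings of the quantification are not given in the sources used here, so genes that overlap, antisense pairs and near-identical copies such as histones and small RNA families are uncertain. A gene listed at 0 may be a dropout of transcript assembly or read assignment and not absent.

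Coverage multiplied by transcript length gave 2.341 to 2.965 Gb (gigabases) per library. With reads taken as 50 bases long, an assumption because the read length is not given in the sources used here, that equals 46.8 to 59.3 M reads. Between 12172 and 13543 genes had at least 1 FPKM. Genes whose longest transcript was under 400 nt (8641 genes) took 8.52 to 16.92% of the bases and 53.28 to 69.84% of the summed FPKM. Because these short features weigh on the deposited scale, gene values were rescaled. Mitochondrial transcripts took 1.24 to 3.43% of the bases and the 10 most covered genes 9.82 to 16.61%. No library was a near copy of another, since the lowest chi-square per gene between any pair was 19.87.

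FPKM was summed over the transcripts of each gene and rescaled by median-of-ratios factors (0.873 to 1.127, from 15551 genes above 0 in all 12 libraries). Genes with at least 1 rescaled FPKM in at least 2 libraries were tested, 13793 in all. The test was limma 3.58.1 in R 4.3.3 with trended and robust variance moderation, on log2(rescaled FPKM + 0.5), with 6 group means fitted to all 12 libraries. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and adjusted p-values below come from this test unless another is named. Fold changes are on the log2(value + 0.5) scale and understate the change of low genes. Tables were read and figures drawn with Python 3.11.15. The test was checked on simulated data for ET-1 against vehicle over 13793 genes, of which 200 were changed. It recovered 64% of genes changed by a log2 of 1 and 87% of those changed by 2, with 1 false call. With the replicate number as a block it recovered 95% and 98%, with 12 false calls. Differences between JQ1 effects of those sizes were recovered in 34% and 71% of genes without the block and in 79% and 93% with it. The simulated noise was independent, with the spread of the fit with the block, and each gene had one shift between replicates. Such data obey the model with the block, so its higher recovery was built in. The shares are therefore not the power of either fit on the real data.

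Replicate numbers are shared by all groups, and the labels do not say what a number marks. In the data, same-numbered libraries deviated together: over all 15 pairs of groups the deviations from the group means correlated at 0.16 to 0.67. The numbers were therefore taken to pair the libraries, from the data and not from the labels, before calls were compared. The fit with the replicate block, set down as an alternative before the data were examined, is given beside a result where it changes a call or moves a count by over 1.5 times. Outside the section on flagged results, fits with a library left out did not use the block unless this is said. Leaving out a library leaves the replicate numbers unbalanced between groups.

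The comparisons were ET-1 and PE against vehicle, without and with JQ1, PE against ET-1, JQ1 against DMSO in each of the 3 treatments, and the differences between those JQ1 effects. Genes were named by a rule: the 10 largest rises and 10 largest falls among called genes with a proper symbol and groups that did not overlap, or 5 and 5 for the agonists with JQ1 and for differences of JQ1 effects. Up to 4 members with the smallest p in each gene list were added, and always Nppa, Nppb, Myh6, Myh7, Acta1, Ankrd1, Hexim1, Cdk9, Ednra, Adra1a and Adra1b. Some were left out from the end of a ranking, and a few genes that the rule or the lists name are not reported here, though they stay in all counts.

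In all, 28 gene lists were tested. They covered hypertrophy and fetal genes, sarcomere, calcium handling and ion channels, immediate early genes and AP-1, ERK feedback and targets, cAMP and CREB targets, SRF and YAP targets, extracellular matrix and secreted growth factors. NF-kB and chemokines, interferon response, cell cycle, ribosome biogenesis, sterol biosynthesis, fatty acid oxidation, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, unfolded protein and integrated stress response and heat shock followed. The rest were P-TEFb with the super elongation complex and BET proteins, genes known to rise with BET inhibitors, receptors and G protein signalling, replication-dependent histones, and markers of fibroblasts, smooth muscle and pericytes, endothelium and macrophages. Of 515 listed symbols 19 were not matched and not used here, among them Ttn, Cd36 and Pecam1. List counts are given over all genes tested and adjusted over the list alone. Limma's camera compared each list with all other genes at a preset correlation of 0.01, adjusted over the 28 lists of a comparison. It called 104 of 308 list results, of which 0 hold with an estimated correlation. Over all 308, 22 had an unadjusted p under 0.05 with that correlation. Fry, which asks only whether a list's genes move one way on balance, was also run.

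Lists, the naming rule, groups, tests and most alternatives were set before the data were examined. Alternatives were pseudocounts of 0.1 and 1, FPKM as deposited, quantile normalization, no filter on low values, a mean of at least 5, limma-voom on reads estimated from coverage, plain variance moderation, only the libraries compared, the replicate block, and each library left out. For unchanged groups against shared vehicle libraries, 100 simulations gave the correlation expected without any effect.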

Results

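The study asked how neonatal rat cardiomyocytes respond to agonists of distinct G protein-coupled receptors, and its title places the elongation factor P-TEFb at the centre of the hypertrophic response. ET-1 acts on endothelin receptors and PE on alpha-1 adrenergic receptors. JQ1 displaces the BET proteins from acetylated chromatin. RNA was sequenced after 24 h in 6 groups of 2 libraries each: vehicle, ET-1 and PE, without and with JQ1. Coverage summed to 2.341 to 2.965 Gb per library. The first principal component, with 54.8% of the variance, set the 6 libraries without JQ1 (−31.3 to −44.8) apart from the 6 with JQ1 (29.3 to 51.2). The second, with 17.8%, was higher in replicate 1 than in replicate 2 of every group (vehicle 27.6 and 4.9, ET-1 3.5 and −30.7). It was also higher in vehicle than with either agonist within each replicate, without and with JQ1. On the next, with 11%, vehicle lay above both agonists within each replicate, and replicate 2 lay above replicate 1 in every group. Levels below are rescaled FPKM as mean ± SD with n = 2 in every group, and changes are log2 differences ± SE.

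The first comparison asked which transcripts ET-1 changed in the absence of JQ1. Bdkrb2, the bradykinin B2 receptor (chromosome 6, 129399468 to 129429676, plus strand), rose from 0.828 ± 0.664 to 6.86 ± 2.73, a change of 2.52 ± 0.49 (adjusted p = 0.041). Sema3c, a secreted guidance protein, rose from 11.2 ± 3.47 to 50.1 ± 14.6 (2.12 ± 0.35, adjusted p = 0.026), and Phf24, Pxdc1 and Wfdc1 rose by 2.25, 1.92 and 1.89. Gamt, which makes creatine, fell from 30.9 ± 4.29 to 6.18 ± 1.07 (−2.24 ± 0.26, adjusted p = 0.012), and Bcl2l11, which encodes the pro-apoptotic protein Bim, fell from 20.9 ± 5.37 to 4.61 ± 0.0146 (−2.04 ± 0.22, adjusted p = 0.012). Doc2g, Klhl33, Crybb1 and the M-band gene Myom3 fell by 2.31, 2.23, 2.2 and 2.14 on the log2 scale. Sct, the secretin gene, stood at 1.51 in vehicle and was listed at 0 with ET-1. Adra1b, the alpha-1B adrenergic receptor, fell from 11.9 ± 1.75 to 4.31 ± 0.63 (−1.37 ± 0.2, adjusted p = 0.022). Of 13793 genes, 180 rose and 216 fell, 55 and 71 of them at least 2-fold. With the replicate block 1226 rose and 1311 fell, and all 396 genes called without the block were among them. Without replicate 1 or replicate 2 of the vehicle 0 genes were called by limma, without those of ET-1 47 and 2, while 2800 genes had an unadjusted p under 0.05 with all libraries. A fit of only the compared libraries called 0 genes, and the values as deposited gave 208. The fits with a library left out did not use the block, although the replicate numbers pair the libraries in the data. The genes called without ET-1 replicate 2 were not among those called with all libraries.

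The classical hypertrophy markers were higher with ET-1 by large factors, but their spread kept them from passing over all genes. Nppb, the gene of B-type natriuretic peptide (ENSRNOG00000008141, chromosome 5, 164796185 to 164797531, plus strand), stood at 3000 ± 747 against 610 ± 284 in vehicle, a difference of 2.36 ± 0.56 (adjusted p = 0.064). Ankrd1 (ENSRNOG00000018598, chromosome 1, 254726969 to 254735548, minus strand), a muscle stress protein, differed by 1.65 ± 0.39 (adjusted p = 0.063), and Acta1 (ENSRNOG00000017786, chromosome 19, 56674074 to 56677084, minus strand), skeletal actin, by 1.9 ± 0.51 (adjusted p = 0.09). Nppa, the atrial peptide, differed by 1.62 ± 0.53 (adjusted p = 0.14). With the replicate block these genes passed, with adjusted p of 0.00091 for Nppb, 0.0009 for Ankrd1, 0.011 for Acta1 and 0.0011 for Nppa. Hopx differed by −1.07 (adjusted p = 0.066, 0.023 with the block) and Hexim1, an inhibitor of P-TEFb, by −0.45 (adjusted p = 0.13, 0.043 with the block). The myosin heavy chains Myh6 (0.11) and Myh7 (0.33), Cdk9 (−0.17), Ednra (−0.24) and Adra1a (0.56) were not called, with adjusted p from 0.26 to 0.93. Of the 14 hypertrophy and fetal genes none passed over all genes, 5 were higher and 1 lower adjusted over the list alone, and 10 and 1 with the block. Their median was 1 (camera adjusted p = 0.00084, adjusted p = 0.8 with an estimated correlation). In fits without the replicate block, leaving out either vehicle library lost every call over all genes. Fits that also used the block kept calls, in the ranges given further below.

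Sterol biosynthesis genes were called higher with ET-1. All 21 tested genes of the pathway had positive differences (median 0.86), 3 rose over all genes, 5 adjusted over the list alone and 11 with the block (camera adjusted p = 1.9e-07, adjusted p = 0.72 with an estimated correlation). Mvd, an enzyme of the mevalonate pathway, rose from 14.3 ± 1.08 to 28.4 ± 3.54 (0.96 ± 0.12, adjusted p = 0.014). All 22 fatty acid oxidation genes had negative differences (median −0.41). Of these Plin5 fell over all genes (−1.28, adjusted p = 0.035), 6 fell adjusted over the list alone and 9 with the block (camera adjusted p = 1.7e-05, adjusted p = 0.67 with an estimated correlation). SRF and YAP targets had a median of 0.32, with 7 of 18 higher adjusted over the list alone against none over all genes and 9 with the block (camera adjusted p = 0.00068, adjusted p = 0.31 with an estimated correlation). ERK feedback genes had a median of 0.57, Spry2 rose (0.88, adjusted p = 0.022), and 4 were higher and 1 lower of 15 adjusted over the list alone, 8 and 1 with the block (camera adjusted p = 0.0024, adjusted p = 0.72 with an estimated correlation). Among 18 immediate early genes (median 0.42) Maff rose (1.18, adjusted p = 0.034), 3 rose adjusted over the list alone and 8 with the block (camera adjusted p = 0.0064, adjusted p = 0.46 with an estimated correlation). In fits without the replicate block, none of the single genes named here was called over all genes without a vehicle library.

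Smaller shifts were called for 4 further lists with ET-1, none with a member past the threshold over all genes. Secreted growth factors had a median of 0.39, with 3 of 16 higher adjusted over the list alone and 5 with the block (camera adjusted p = 0.022, adjusted p = 0.45 with an estimated correlation). Ribosome biogenesis had a median of 0.27 with 22 of 25 positive, none adjusted over the list alone and 2 with the block (camera adjusted p = 0.0089, adjusted p = 0.96 with an estimated correlation). Calcium handling genes had a median of −0.4, none adjusted over the list alone, and 2 higher and 4 lower of 23 with the block (camera adjusted p = 0.006, adjusted p = 0.91 with an estimated correlation). P-TEFb and BET genes had a median of −0.16, none adjusted over the list alone and 6 of 23 lower with the block (camera adjusted p = 0.0049, adjusted p = 0.45 with an estimated correlation). Camera also called, once the block was used, interferon genes (median −0.25, adjusted p 0.25 to 0.034), mitochondrially encoded genes (−0.36, 0.06 to 0.00021, and without the block 0.0054 on the values as deposited) and fibroblast markers (−0.47, 0.79 to 0.0016). With the block and an estimated correlation their adjusted p were 0.57, 0.39 and 0.39. The other lists were not called: sarcomere (median 0.11), cAMP and CREB targets (0.03), NF-kB (0), glycolysis (0.07), oxidative phosphorylation (0.06), unfolded protein response (−0.07), heat shock (0.16), genes known to rise with BET inhibitors (−0.21), receptors (−0.12), endothelial (−0.15) and macrophage markers (−0.22), and histones (−0.01). Extracellular matrix (median −0.03, mean 0.03), cell cycle (−0.03, 0.07) and smooth muscle markers (−0.29, 0.06) had medians and means of opposite sign, with the test following the mean.

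PE was compared with vehicle in the same way. Nppb rose from 610 ± 284 to 3280 ± 1380 (2.44 ± 0.56, adjusted p = 0.044), Acta1 from 374 ± 245 to 1700 ± 30.1 (2.36 ± 0.51, adjusted p = 0.036) and Ankrd1 from 1500 ± 520 to 5260 ± 1250 (1.84 ± 0.39, adjusted p = 0.034). Bdkrb2 rose by 3.28 ± 0.49, and Wfdc1 (ENSRNOG00000015904, chromosome 19, 52313795 to 52332697, plus strand), a small secreted protein, rose from 1.44 ± 0.247 to 12.6 ± 0.721 (2.76 ± 0.21, adjusted p = 0.0039). Sema3c rose by 2.37 and Tnfrsf12a, the TWEAK receptor, by 2.18. A copy of the small RNA family RF00017 rose by 2.4, which is uncertain because its reads may be shared between copies. Crybb1, Klhl33, Myom3, Doc2g and the GABA receptor subunit Gabrb2 fell by 2.42, 2.37, 2.22, 2.2 and 2.19 on the log2 scale. Gamt fell by 2.16 on the log2 scale. Adra1b fell by 1.15 (adjusted p = 0.021) and Hopx by 1.16 (adjusted p = 0.038). Nppa differed by 1.39 ± 0.53 (adjusted p = 0.16, 0.001 with the block) and Adra1a by 0.72 (adjusted p = 0.26, 0.019 with the block). Myh6 (0.16), Myh7 (0.37), Hexim1 (−0.39), Cdk9 (−0.2) and Ednra (−0.32) were not called. In all, 398 genes rose and 439 fell, 105 and 122 of them at least 2-fold, while a fit of only the compared libraries called 0. With the block 1627 rose and 1687 fell, including all 837 called without it. Left-out libraries moved the count to 80 (vehicle replicate 1), 10 (vehicle replicate 2), 144 (PE replicate 1) and 3 (PE replicate 2). On the values as deposited 532 genes were called and the share that rose was 35.3% in place of 47.6%, with the median of all genes at −0.13.

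Hypertrophy, sterol and signalling genes were called higher with PE. Hypertrophy and fetal genes had a median of 1.03, with 3 higher and 1 lower over all genes, 4 and 1 adjusted over the list alone and 10 and 1 with the block (camera adjusted p = 0.0013, adjusted p = 0.6 with an estimated correlation). Sterol genes had a median of 0.88, with 4 higher, 6 adjusted over the list alone and 16 with the block (camera adjusted p = 3.4e-07, adjusted p = 0.6 with an estimated correlation), among them Idi1, which rose from 39.8 ± 0.758 to 135 ± 16.5 (1.75, adjusted p = 0.044). Immediate early genes had a median of 0.54, with 4 higher, 6 adjusted over the list alone and 12 with the block (camera adjusted p = 0.00021, adjusted p = 0.25 with an estimated correlation). Fos rose from 3.34 ± 0.882 to 8.86 ± 1.1 (1.3, adjusted p = 0.026), and Maff and Ier3 by 1.15 and 1.14. ERK feedback genes had a median of 0.72, with 3 higher against 6 higher and 1 lower adjusted over the list alone and 9 and 1 with the block (camera adjusted p = 0.0022, adjusted p = 0.6 with an estimated correlation). SRF and YAP targets had a median of 0.37, with 3 higher, 5 adjusted over the list alone and 9 with the block (camera adjusted p = 2e-04, adjusted p = 0.23 with an estimated correlation). The cAMP and CREB targets, led by the kinase Sik1 (1.77, adjusted p = 0.018) and Bdnf (0.89), had a median of 0.56, with 2 of 13 higher, 5 higher and 1 lower adjusted over the list alone and 6 higher with the block (camera adjusted p = 0.013, adjusted p = 0.25 with an estimated correlation). Without PE replicate 2 and without vehicle replicate 2, 3 and 10 genes in all were called over all genes.

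Metabolic and channel genes were called with PE in both directions. Fatty acid oxidation had a median of −0.34, with 2 lower (Ech1, −1.54, and Plin5, −1.26), 3 adjusted over the list alone and 7 with the block (camera adjusted p = 0.0013, adjusted p = 0.6 with an estimated correlation). Glycolysis had a median of 0.23, where the lactate transporter Slc16a3 rose (1.57, adjusted p = 0.013), 5 were higher and 1 lower adjusted over the list alone and 5 and 2 with the block (camera adjusted p = 0.016, adjusted p = 0.6 with an estimated correlation). Calcium handling had a median of −0.45, with the channel subunit Kcnip2 lower (−2.11, adjusted p = 0.046) and the exchanger Slc8a1 higher (0.54, adjusted p = 0.048), 2 higher and 4 lower adjusted over the list alone, and 4 and 6 with the block (camera adjusted p = 0.0057, adjusted p = 0.67 with an estimated correlation). P-TEFb and BET genes had a median of −0.2, with Ell and Mllt3 lower and Eaf1 higher, 1 higher and 5 lower adjusted over the list alone and 1 and 8 with the block (camera adjusted p = 0.0057, adjusted p = 0.3 with an estimated correlation). None passed over all genes in the next 7 lists. Histone genes had a median of −0.4 with 0 of 34 positive and none adjusted over the list alone, against 7 lower with the block (camera adjusted p = 1.8e-06, adjusted p = 0.6 with an estimated correlation), and their near-identical copies make single genes uncertain. Mitochondrially encoded genes had a median of −0.56, none adjusted over the list alone and 10 of 13 lower with the block (camera adjusted p = 0.01, adjusted p = 0.69 with an estimated correlation). Ribosome biogenesis (0.28, adjusted p = 0.0046), secreted factors (0.37, 0.028), heat shock (0.22, 0.027) and sarcomere (0.22, 0.043) were called higher, and genes known to rise with BET inhibitors lower (−0.32, 0.027, but 0.11 on the values as deposited). With an estimated correlation their adjusted p were 0.69, 0.37, 0.41, 0.81 and 0.6, and adjusted over the list alone 0, 4, 2 and 0 members were higher and 1 was lower. With the block, camera also called interferon genes (median −0.34, adjusted p 0.07 to 0.0066), fibroblast markers (−0.34, 0.88 to 0.029) and macrophage markers (−0.36, 0.46 to 0.029), at adjusted p = 0.42, 0.42 and 0.34 with an estimated correlation. Not called were cell cycle (0.09, where Aurka and Ccnb1 rose by 0.46 and 0.42), oxidative phosphorylation (0.07), unfolded protein response (0.05), receptors (−0.07) and endothelial markers (−0.16). On the values as deposited NF-kB genes (0.1, adjusted p 0.097 to 0.03) and extracellular matrix (0.26 to 0.044) were called too. Extracellular matrix (median −0.15, mean 0.05) and smooth muscle markers (−0.04, 0.13) had medians and means of opposite sign. Over all genes, 144 and 3 genes in all were called without replicate 1 and replicate 2 of PE.

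**Figure D1:**
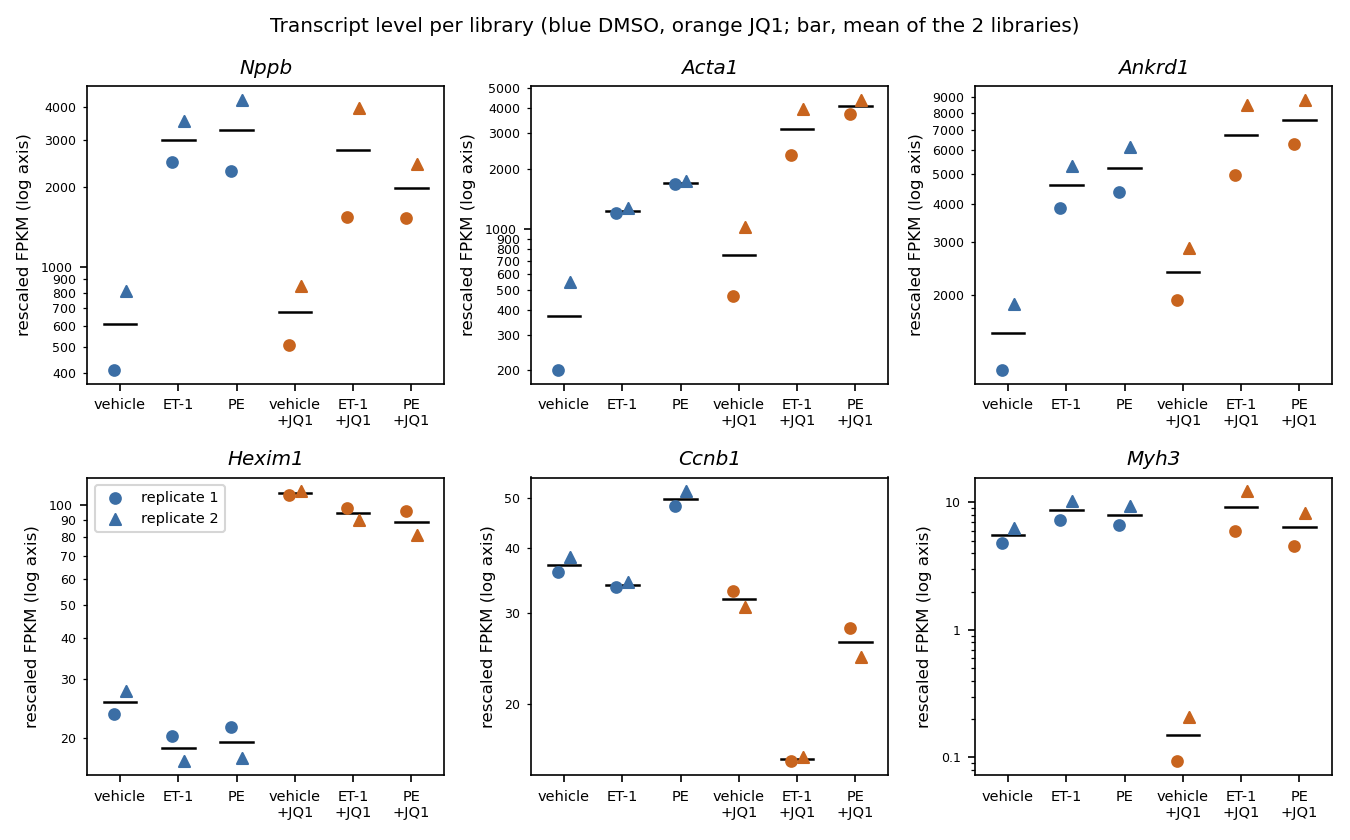
Rescaled FPKM (log axis) of Nppb, Acta1, Ankrd1, Hexim1, Ccnb1 and Myh3 in each of the 12 libraries by group, with circles for replicate 1, triangles for replicate 2, blue for DMSO, orange for JQ1 and bars for the mean of 2. Nppb lay at 410 and 811 in vehicle and at 2300 to 4250 with an agonist alone, Hexim1 at 17 to 27.6 without JQ1 and 81 to 110 with it, and Myh3 at 0.0927 and 0.209 in vehicle with JQ1 against 4.57 to 12.3 in the other groups.

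The direct comparison of PE with ET-1 asked whether the receptors gave different responses. Across 13793 genes the ET-1 and PE responses correlated at 0.89 (0.76 in replicate 1 and 0.89 in replicate 2), with a slope of 0.95, and genes are not independent replicates. Both shared the vehicle libraries, which alone gave a correlation of 0.51 in simulations of unchanged groups. The covariance was 0.15 against a simulated 0.024, a difference of 0.13. Called in both were 158 higher and 205 lower genes, with none in opposite directions, where independent lists would share 5.2 and 6.9. With ET-1 taken from one replicate and PE from the other, which share no library, the correlations were 0.48 and 0.58 and the covariances 0.1 and 0.12, each from single libraries. Part of the excess of genes called in both may come from the shared vehicle libraries. A single gene was called between PE and ET-1, the placeholder AABR07034673.1 (ENSRNOG00000059680, chromosome 11, 83483172 to 83483513), which was named after its values were seen. It stood at 2.42 with ET-1 and 2.32 in vehicle and was listed at 0 with PE and in all JQ1 groups (adjusted p = 0.0037). The call rests on these 0 values of a transcript of 321 nt, which may be a dropout of the quantification. A fit of only the libraries compared did not call it and called 1 other gene. Without PE replicate 1 the count was 0, without ET-1 replicate 1, ET-1 replicate 2 or PE replicate 2 it was 3, 2 and 3, and 206 genes had an unadjusted p under 0.05 (652 with the block). Nppb (0.08 ± 0.56), Nppa (−0.24 ± 0.53), Acta1 (0.46 ± 0.51), Ankrd1 (0.19 ± 0.39), Hexim1 (0.06 ± 0.14), Adra1a (0.16 ± 0.34) and Adra1b (0.21 ± 0.2) had adjusted p of 1, which leaves differences of the size of these errors open in the fit without the block. In the same order the SE with the replicate block were 0.19, 0.14, 0.34, 0.13, 0.12, 0.17 and 0.18. None of these genes was called there either, and differences of that smaller size stay open.

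Histone transcripts had a median of −0.36 in PE relative to ET-1, with 0 of 34 positive (camera adjusted p = 4.9e-25, adjusted p = 0.42 with an estimated correlation). The cAMP and CREB targets were 0.33 higher with PE, 11 of 13 positive (camera adjusted p = 8.4e-06, adjusted p = 0.052 with an estimated correlation). Immediate early genes (0.14, camera adjusted p = 0.0034) and glycolysis (0.11, 0.00068) were also higher with PE, at adjusted p = 0.42 and 0.67 with an estimated correlation. NF-kB (0.07, 0.025), unfolded protein response (0.2, 0.036), cell cycle (0.11, 0.036) and, downward, genes known to rise with BET inhibitors (−0.15, 0.025) were called, each at adjusted p = 0.97 with an estimated correlation. The calls of cell cycle and of the BET inhibitor list were lost on the values as deposited (0.13 each), where sarcomere (0.28 to 0.042) and mitochondrial genes (0.16 to 0.042) were called. With the block mitochondrial genes (median −0.11, adjusted p 0.16 to 0.0013), interferon genes (−0.11, 0.33 to 0.038) and fibroblast markers (0.1, 0.9 to 0.038) were called as well, at adjusted p = 0.7 each with an estimated correlation. Among all members of these lists, none was called over all genes, and Ccnb1 (0.54 ± 0.09, adjusted p = 0.9) was higher adjusted over the list alone.

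More genes were called for JQ1 than for either agonist. In vehicle-treated cells Hexim1 (ENSRNOG00000003203, chromosome 10, 91200874 to 91202984, plus strand), a known marker of BET inhibition, rose from 25.6 ± 2.78 to 108 ± 1.86 (2.07 ± 0.14, adjusted p = 0.00011), and Brd2 from 16.6 ± 1.53 to 56.3 ± 0.11 (1.73 ± 0.08, adjusted p = 3e-05). Serpini1, known to rise with BET inhibitors, rose by 2.21 ± 0.27, and Entpd5, Hap1, Nap1l5 and Gpr137c by 2.08, 2.21, 2.46 and 2.48. Asb9, a substrate adaptor of ubiquitin ligases (chromosome X, 31700633 to 31780425, minus strand), fell from 17.2 ± 3.67 to 0.15 ± 0.0132 (−4.75 ± 0.2, adjusted p = 2.6e-05). The added 0.5 makes this log2 change smaller than the ratio of the 2 levels. The phospholipase gene Pla2g5 fell from 39.7 ± 3.62 to 1.67 ± 0.378 (−4.22 ± 0.48), and Lsmem1, Dhrs7c, Smim5 and Tmem182 fell by 4.02, 3.9, 3.84 and 3.74 on the log2 scale. Of 13793 genes, 2112 rose and 2299 fell, and of those at least 2-fold 221 rose and 883 fell. With the block 3428 rose and 3851 fell, including all 4411. Without vehicle replicate 1, vehicle replicate 2, or replicate 1 of vehicle with JQ1, 2873, 2758 and 2583 genes were called, and 2933 in a fit of the compared libraries alone. The share of called genes that rose, 47.9%, was 31.5% with the deposited scaling, 55.5% with quantile normalization and 58.5% at a mean of at least 5.

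JQ1 was also compared with DMSO in ET-1 and in PE. Hexim1 rose from 18.6 ± 2.32 to 94.2 ± 5.58 in ET-1 (2.31 ± 0.14) and from 19.5 ± 2.95 to 88.5 ± 10.7 in PE (2.16 ± 0.14), and Brd2 rose by 2.03 and 2.01. Smim5 (ENSRNOG00000049642, chromosome 10, 104451222 to 104457001, plus strand), a small membrane protein, fell from 32.4 ± 6.8 to 0.422 ± 0.0918 in ET-1 (−5.15 ± 0.18, adjusted p = 1.3e-05) and by 4.76 on the log2 scale in PE. Pla2g5 fell by 4.75 and 5.13, and Wfdc1, which had risen with PE, fell from 12.6 ± 0.721 to 0.106 ± 0.149 (−4.46 ± 0.21, adjusted p = 2.3e-05). Gclc, the rate-limiting enzyme of glutathione synthesis, rose in ET-1 from 16 ± 2.26 to 70 ± 27.4 (2.05, adjusted p = 0.0013). Coa6, ranked first among the rises in PE, was listed at 0 in both PE libraries and in ET-1 replicate 1, at 9.6 in ET-1 replicate 2, at 9.86 and 8.72 in vehicle and at 6.38 to 8.14 with JQ1. Such a 0 may come from the assembly or assignment of reads to transcripts and not from absence, so no fold is given. In ET-1 2471 genes rose and 2697 fell (293 and 1169 at least 2-fold), and in PE 2415 and 2615 (309 and 1052). With the block the counts were 3740 and 4109 in ET-1 and 3680 and 4102 in PE, with all genes called without it included. Without PE replicate 2 the PE count was 3313, and fits of the compared libraries alone called 2346 genes in ET-1 and 3124 in PE. The share that rose, 47.8% in ET-1 and 48% in PE, was 32% and 38.9% with the deposited scaling, 55.5% and 55.2% with quantile normalization and 55.9% and 55.3% at a mean of at least 5. JQ1 changes correlated across genes at 0.88 between vehicle and ET-1, 0.85 between vehicle and PE, and 0.92 between ET-1 and PE, in comparisons without a common library. Called in both vehicle and ET-1 were 1795 higher and 2001 lower genes, with none opposite, where independent lists would share 378.4 and 449.5. Vehicle and PE shared 1749 and 1911 (369.8 and 435.9), and ET-1 and PE shared 2096 and 2362 with 1 opposite (432.6 and 511.3).

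None of the induced hypertrophy markers was called lower with JQ1 without the replicate block. Nppb stood at 678 ± 240 in vehicle with JQ1 (0.19, adjusted p = 0.83), at 2750 ± 1710 in ET-1 with JQ1 (−0.26, adjusted p = 0.75) and at 1980 ± 630 in PE with JQ1 (−0.7 ± 0.56, adjusted p = 0.37, 0.015 with the block). Acta1 was higher with JQ1, by 1.06, 1.3 and 1.25 in vehicle, ET-1 and PE (adjusted p = 0.15, 0.08 and 0.089, and 0.033, 0.013 and 0.015 with the block), and was called in vehicle without vehicle replicate 2. Ankrd1 differed by 0.69, 0.51 and 0.52 (adjusted p = 0.21, 0.33 and 0.33, and 0.003, 0.01 and 0.0097 with the block). Nppa (0.43, −0.14 and −0.15), Myh6 (0.1, 0.05 and −0.07) and Myh7 (−0.43, −0.04 and −0.23) were not called, and with the block only Nppa and Myh7 in vehicle were (adjusted p = 0.03 and 0.046). The hypertrophy and fetal list was not called (medians 0.17, 0.2 and 0.19, adjusted p = 0.85, 0.56 and 0.73), and its median in ET-1 was −0.01 under quantile normalization.

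Cdk9, the kinase of P-TEFb, rose by 0.42 in ET-1 (adjusted p = 0.004) and 0.4 in PE (0.0053), and by 0.35 in vehicle (0.011). The call in vehicle was lost without vehicle replicate 2 (0.34) and without replicate 1 or 2 of vehicle with JQ1 (0.36 and 0.35). The endothelin A receptor Ednra fell in ET-1 from 23.9 ± 5.56 to 4.56 ± 2.64 (−2.36 ± 0.37, adjusted p = 0.002). In vehicle it fell by 1.27 (adjusted p = 0.034), a call lost without vehicle replicate 1 (−0.88) or either JQ1 library (−1.43 and −1.10 for replicates 1 and 2). In PE it fell by 1.11 (adjusted p = 0.048), a call lost without any of the 4 libraries, PE or PE with JQ1 (−1.03 to −1.20). Adra1a fell in PE by 1.67 (adjusted p = 0.0066), in ET-1 by 1.46 (0.012, lost without ET-1 replicate 2, −1.03, or replicate 1 of ET-1 with JQ1, −1.3) and in vehicle by 1.18 (0.032, lost without any of its 4 libraries, −0.94 to −1.43). Adra1b fell in vehicle by 0.98 (0.0083, lost without vehicle replicate 2, −0.83, or replicate 1 of vehicle with JQ1, −0.91). In PE it fell by 0.62 (0.045, lost without any of the PE and PE with JQ1 libraries, −0.45 to −0.78), and in ET-1 it was not called (−0.31). Among the 23 P-TEFb and BET genes, 10, 12 and 12 rose and 3, 3 and 2 fell in vehicle, ET-1 and PE, and 12, 13 and 12 rose and 4, 4 and 3 fell adjusted over the list alone. The medians were 0.25, 0.34 and 0.33, not called in vehicle (camera adjusted p = 0.06) and called in ET-1 (0.018) and PE (0.012), at adjusted p = 0.7 and 0.59 with an estimated correlation. Hexim2 (−1.34 in vehicle) and the NELF subunit Nelfcd (−0.74, −0.91 and −0.83) fell. Of 6 genes known to rise with BET inhibitors 3 rose in each treatment, also adjusted over the list alone, with medians of 0.66, 0.52 and 0.87. That list was called in vehicle (0.039) and PE (0.019) at adjusted p = 0.89 and 0.82 with an estimated correlation, and in ET-1 only with the block (0.068 to 0.039, adjusted p = 0.57 with an estimated correlation). The receptor list was not called (medians −0.29, −0.25 and −0.27), with 2, 3 and 3 higher and 4, 5 and 6 lower of 20.

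Of 28 cell cycle genes tested, 16 fell with JQ1 in vehicle, 28 in ET-1 and 26 in PE, and 20, 28 and 27 adjusted over the list alone, with none higher. Medians were −0.63, −1.3 and −1.03 (camera adjusted p = 6.6e-06, 3.9e-15 and 1.9e-12, adjusted p = 0.89, 0.7 and 0.61 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, fell from 24.5 ± 0.494 to 12.1 ± 0.443 in vehicle (−0.99 ± 0.14), from 23 ± 3.39 to 5.95 ± 0.82 in ET-1 (−1.87 ± 0.14) and from 26.9 ± 2.27 to 8 ± 1.13 in PE (−1.69 ± 0.14). Mitotic Plk1 fell by 0.71, 1.39 and 1.27 on the log2 scale. Of 34 histone genes 14, 23 and 15 fell and Hist1h1c rose in each, the same counts adjusted over the list alone, with medians of −0.43, −1.05 and −0.46 (camera adjusted p = 0.025, 7.4e-07 and 0.0044, adjusted p = 0.89, 0.71 and 0.82 with an estimated correlation), and the call in vehicle was lost on the values as deposited (0.062). The rise of Hist1h1c in ET-1 was not called without ET-1 replicate 2 (0.53). Reads of near-identical histone copies cannot be placed with certainty.

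Of 28 nuclear genes of oxidative phosphorylation 5, 17 and 18 fell in vehicle, ET-1 and PE (4, 21 and 20 adjusted over the list alone), with medians of −0.31, −0.6 and −0.64 (camera adjusted p = 0.015, 1.3e-05 and 3.8e-06, adjusted p = 0.89, 0.71 and 0.82 with an estimated correlation). Ndufs1 fell by 0.68, 0.88 and 0.81 on the log2 scale. Eno3, the muscle enolase, fell in vehicle from 200 ± 25.7 to 31.8 ± 10.3 (−2.67 ± 0.27, adjusted p = 0.00048), and the insulin-sensitive glucose carrier Slc2a4 by 1.8. Glycolysis as a list had medians of −0.18, −0.42 and −0.45, with 4, 8 and 6 of 20 lower and 1 higher in vehicle, and was called in ET-1 (0.032) and PE (0.035) at adjusted p = 0.71 and 0.82 with an estimated correlation. Cpt1b, which carries fatty acids into mitochondria, fell by 2.34, 2.47 and 2.24, and Acot2 by 1.67, 2.01 and 1.99. The fatty acid oxidation list was not called (medians −0.36, −0.39 and −0.22, adjusted p = 0.06, 0.07 and 0.13), with 8, 9 and 8 lower and 1, 2 and 2 higher of 22. Sterol genes, with a median of −0.12 in vehicle (adjusted p = 0.85), were called lower in ET-1 (−0.52, 0.032) and PE (−0.54, 0.033), at adjusted p = 0.82 and 0.89 with an estimated correlation and 0.11 and 0.09 on the values as deposited. Of them 0, 1 and 2 of 21 fell and 12 fell with the block in ET-1 and in PE. Calcium handling genes had medians of −0.31, −0.42 and −0.44, with 6, 7 and 7 of 23 lower and none higher, called in ET-1 (0.012) and PE (0.019) at adjusted p = 0.71 and 0.82 with an estimated correlation. Adjusted over the list alone, 4, 9 and 6 glycolysis genes, 8, 9 and 8 fatty acid oxidation genes, 0, 1 and 1 sterol genes and 6, 7 and 7 calcium handling genes were lower. The potassium channel Kcnj11 fell by 1.93, 2.37 and 2.35 and triadin, Trdn, by 1.43, 2.13 and 2.01.

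Signalling lists moved in both directions. In PE, ERK feedback genes (median −0.56, 5 of 15 lower, 9 lower and 1 higher adjusted over the list alone) and secreted growth factors (−0.71, 5 of 16 lower) were called lower (camera adjusted p = 0.015 and 0.019, adjusted p = 0.82 and 0.59 with an estimated correlation). Etv4 fell by 1.95, 2.87 and 2.89 in vehicle, ET-1 and PE and Inhba, an activin subunit, by 1.77, 2.11 and 2.6. In vehicle and ET-1 the ERK list was not called (−0.37 each, adjusted p = 0.085 and 0.091), and the secreted factors (−0.73 and −0.61, 3 and 5 lower) were called only with the block (0.06 to 0.02 and 0.069 to 0.015). NF-kB genes had medians of −0.46, −0.52 and −0.51 with 5, 5 and 3 of 17 lower. They were called in ET-1 (0.035) and PE (0.048) at adjusted p = 0.71 and 0.82 with an estimated correlation, not on the values as deposited (0.069 and 0.077), and in vehicle only with the block (0.06 to 0.02). Immediate early genes had medians of 0.54, 0.36 and 0.32, with 8, 4 and 4 of 18 higher and 1 lower each, Jund rising by 1.35, 1.34 and 1.51. That list was called with the block in vehicle (0.06 to 0.013, and without the block 0.022 on the values as deposited) and ET-1 (0.13 to 0.039). Heat shock genes had medians of 0.5, 0.45 and 0.51, with 6, 5 and 5 of 11 higher and 1, 1 and 2 lower, called only with the block in ET-1 (0.082 to 0.039) and PE (0.095 to 0.042). Adjusted over the list alone, 3, 5 and 5 secreted factors and 5, 5 and 3 NF-kB genes were lower, and 8, 4 and 4 immediate early genes and 6, 5 and 6 heat shock genes were higher. With an estimated correlation the calls gained with the block in this paragraph had adjusted p of 0.5 to 0.59. Not called in any treatment were sarcomere (−0.12, −0.11 and −0.19), cAMP and CREB targets (−0.29, −0.24 and −0.3), SRF and YAP targets (0.26, 0.29 and 0.13), ribosome biogenesis (0.02, 0.09 and 0.05) and unfolded protein response (−0.32, 0.25 and 0). Under quantile normalization the cAMP medians in vehicle and PE were 0.16 and 0.08, and the mean of the SRF list in PE was −0.09. Mitochondrially encoded genes (0.11, 0.33 and 0.33) were called with the block in ET-1 (0.3 to 0.025) and PE (0.29 to 0.015).

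Markers of other cell types were lower with JQ1 beside these groups. Smooth muscle and pericyte markers had medians of −1.04, −0.85 and −0.98 in vehicle, ET-1 and PE (camera adjusted p = 0.025, 0.032 and 0.015, adjusted p = 0.89, 0.71 and 0.82 with an estimated correlation, and 0.06, 0.058 and 0.022 on the values as deposited). Of 11 tested 3, 4 and 4 fell, 4, 4 and 5 adjusted over the list alone and 10 in each with the block, with Abcc9 at −1.62, −1.36 and −1.3 and Cspg4 at −1.21, −1.75 and −2. These listed members may also be expressed by the cardiomyocytes themselves, which was not tested, so their fall need not concern other cell types. Fibroblast markers had medians of −0.84, −0.66 and −0.65 and macrophage markers of −1.03, −0.87 and −0.91, with no member called. Both lists were called only with the block, at adjusted p of 0.34 to 0.00046, 0.37 to 0.0047 and 0.38 to 0.0056 for fibroblasts and 0.16 to 0.0067, 0.27 to 0.013 and 0.26 to 0.015 for macrophages. Extracellular matrix (−0.72, −0.5 and −0.49, with 3, 1 and 2 of 23 lower, and Lox lower in vehicle, 0.011, a call lost without vehicle replicate 1, −1.37, or replicate 2 of vehicle with JQ1, −1.51) followed the same pattern, 0.15 to 0.00046, 0.3 to 0.0078 and 0.26 to 0.0056. Interferon genes (−0.94, −0.9 and −0.79, with 3, 3 and 4 of 18 lower) did so too, 0.072 to 0.013, 0.078 to 0.012 and 0.18 to 0.032. Adjusted over the list alone 1, 1 and 2 matrix genes and 2, 3 and 2 interferon genes were lower. Ifi44 fell by 1.88, 1.84 and 1.67. With an estimated correlation these blocked calls had adjusted p of 0.5, 0.5 and 0.48 for fibroblast markers, 0.3, 0.48 and 0.35 for macrophage markers, 0.53, 0.57 and 0.51 for matrix and 0.53, 0.57 and 0.59 for interferon genes. Endothelial markers had medians of −0.8, −0.6 and −0.73 and were not called (adjusted p = 0.58, 0.56 and 0.65). These markers also differed between replicates: in every group fibroblast markers were 1.67 to 1.91 higher in replicate 1, macrophage markers 0.88 to 1.16, endothelial markers 0.57 to 0.98 and smooth muscle markers 0.52 to 0.9.

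**Figure D2:**
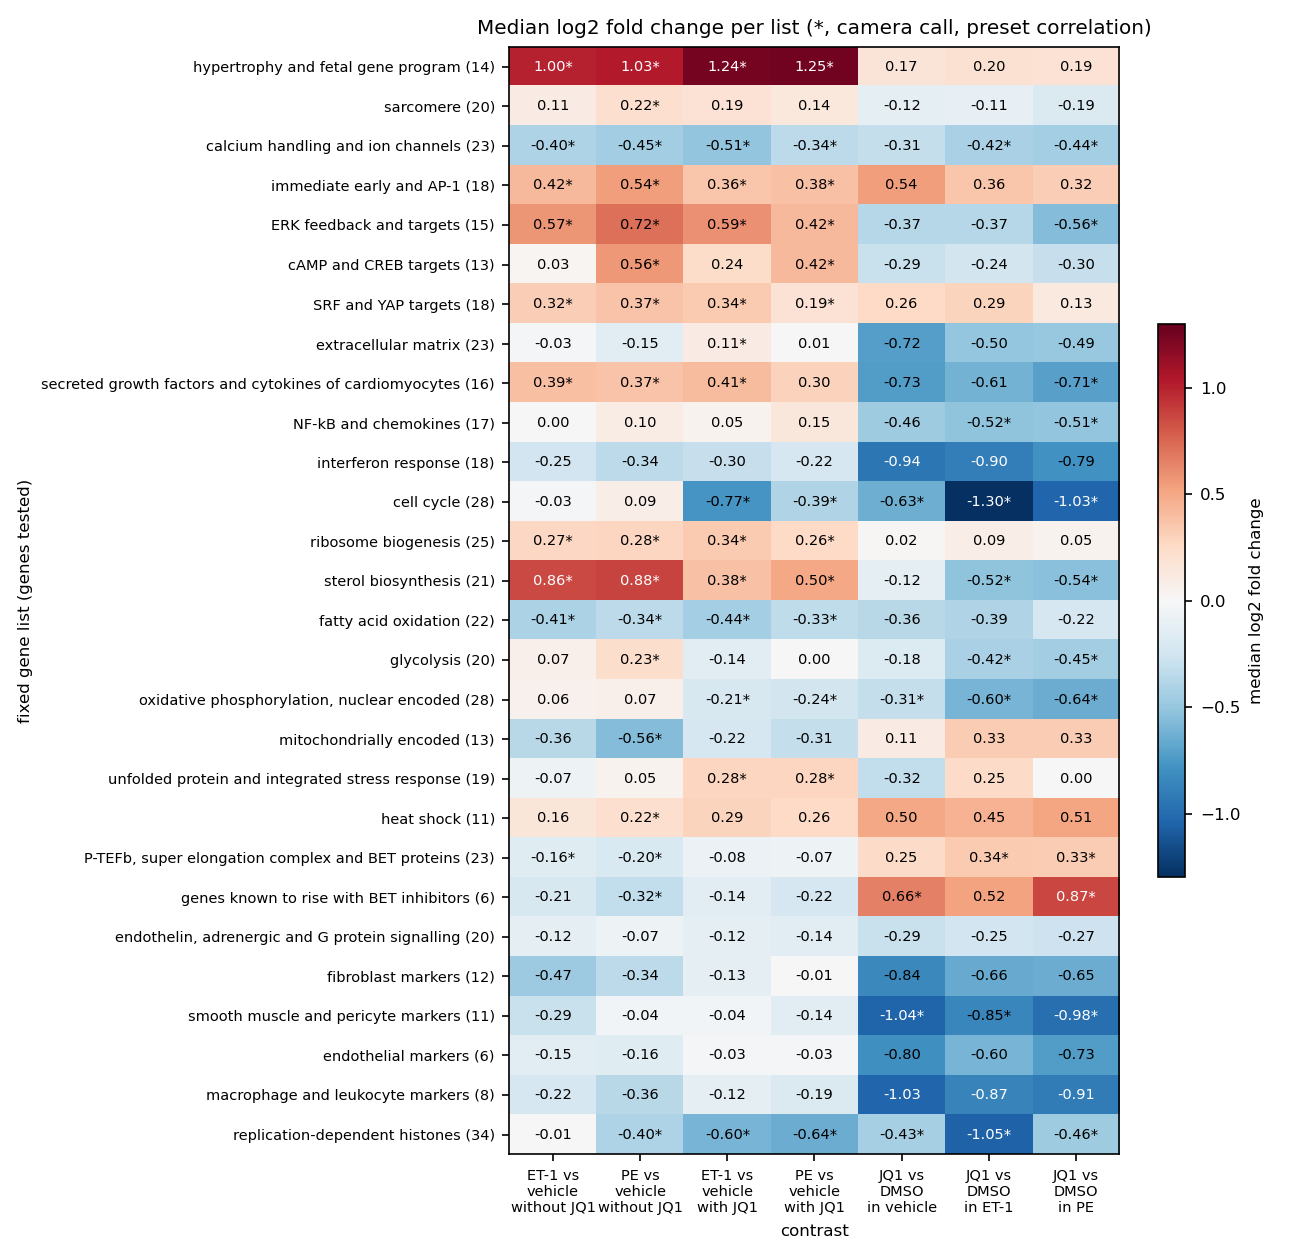
Heatmap of the median log2 difference of each of the 28 gene lists (vertical axis) in 7 comparisons (horizontal axis: ET-1 and PE against vehicle without and with JQ1, and JQ1 against DMSO in vehicle, ET-1 and PE), with colour for the median and an asterisk for a camera call at the preset correlation. Hypertrophy and fetal genes were at 1 to 1.25 with the agonists and at 0.17 to 0.2 with JQ1, where quantile normalization gives −0.01 in ET-1, and cell cycle genes were at −0.63, −1.3 and −1.03 with JQ1.

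The agonists were next compared with vehicle in the presence of JQ1. Myh3, embryonic myosin heavy chain (ENSRNOG00000046276, chromosome 10, 53621375 to 53645194, plus strand), was higher than in vehicle with JQ1 (0.151 ± 0.0822) in both ET-1 (9.18 ± 4.47, 3.82 ± 0.37, adjusted p = 0.013) and PE (6.39 ± 2.58, 3.36 ± 0.37, adjusted p = 0.027). With ET-1 Pxdc1 and the protease inhibitor Timp1 rose by 1.88 and 1.61, Smim5 fell by 2.14 on the log2 scale, Hopx by 1.68, and muscle creatine kinase, Ckm, fell from 340 ± 94.7 to 90.3 ± 36.5 (−1.94 ± 0.33, adjusted p = 0.039). With PE Bok, a Bcl-2 family gene, rose from 21 ± 8.02 to 81.2 ± 7.07 (1.97, adjusted p = 0.033), Eno3 rose by 1.88 and the neurotrophin Ntf3 fell by 1.99 on the log2 scale. Differences of Nppb were 1.91 and 1.56 for ET-1 and PE (adjusted p = 0.14 and 0.23, 0.003 and 0.0059 with the block), of Acta1 2.14 and 2.55 (0.09 and 0.073, 0.011 and 0.0072), of Ankrd1 1.48 and 1.67 (0.11 and 0.094, 0.0018 and 0.0015) and of Nppa 1.06 and 0.81 (0.35 and 0.52, 0.0062 and 0.014). Adra1b differed by −0.7 and −0.79 (0.14 and 0.12, 0.046 and 0.031 with the block), and Myh7 by 0.72 and Ednra by −1.33 with ET-1 (0.35 and 0.13, 0.026 and 0.047 with the block). Hexim1 (−0.2 and −0.3), Cdk9 (−0.11 and −0.16), Myh6 (0.06 and −0.02) and Adra1a (0.28 and 0.23) were not called. In all, 44 genes rose and 143 fell with ET-1 and 53 and 46 with PE, against 679 and 922, and 851 and 813, with the block, where every gene called without it was included. Both agonists shared 20 higher and 36 lower genes (0.2 and 0.5 for independent lists), part of which may come from the shared vehicle libraries, and across replicates, without a shared library, the responses correlated at 0.47 and 0.39. Leaving out either library of vehicle with JQ1 lost every call in fits without the block, while calls remained in fits with it. Both counts without the block were 0 in fits of only the compared libraries. Without replicate 1 and replicate 2 of ET-1 with JQ1 the ET-1 count was 280 and 0, and without those of PE with JQ1 the PE count was 3 and 0. The genes called without replicate 1 of PE with JQ1 were not among those called with all libraries. The deposited scaling gave 25 and 31 called genes, 36% and 71% of them higher in place of 23.5% and 53.5%.

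Agonist responses were compared without and with JQ1 in genes picked in one replicate and measured in the other. Among 200 genes picked for their rise with ET-1 alone, the median difference was 1.11 without and 0.81 with JQ1 (picked in replicate 1), and 0.95 and 0.58 (picked in replicate 2). For 200 picked for their fall the medians were −1.23 and −0.68, and −0.91 and −0.5. With PE the rises were 1.18 and 0.78, and 1.1 and 0.59, and the falls −1.38 and −0.8, and −1.01 and −0.49. In each case 81 to 93% of the picked genes had the same direction with JQ1. Genes picked without JQ1 favour a larger median without it, and a set picked with JQ1, added after the data were seen, did not show smaller responses with JQ1 throughout. There the rises with ET-1 were 0.87 without and 1.07 with JQ1, and 0.69 and 0.63, and the falls −0.6 and −1.02, and −0.6 and −0.64. With PE they were 0.89 and 0.94, 0.67 and 0.78, −0.87 and −1.07, and −0.67 and −0.67. Across all genes the changes with and without JQ1, which share no library, correlated at 0.64 for ET-1 (slope 0.6) and 0.55 for PE (slope 0.47), slopes that noise in the changes without JQ1 lowers. Without and with JQ1 25 genes rose and 40 fell in both with ET-1 (0.6 and 2.2 for independent lists), and 31 and 32 with PE (1.5 and 1.5).

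Hypertrophy and fetal genes had medians of 1.2 with ET-1 and 1.25 with PE, with only Hopx called over all genes, 9 and 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.5e-06 and 4e-05, adjusted p = 0.47 and 0.59 with an estimated correlation). Cell cycle genes were lower with ET-1 (−0.77, 12 lower over all genes and 18 adjusted over the list alone) and PE (−0.39, none and 8), at camera adjusted p = 7.9e-19 and 5.4e-10 and adjusted p = 0.41 and 0.55 with an estimated correlation. Ccnb1 fell with ET-1 from 31.9 ± 1.65 to 15.7 ± 0.168 (−1 ± 0.09, adjusted p = 0.0084). Histones had medians of −0.6 and −0.64, 23 and 18 lower adjusted over the list alone and none over all genes (camera adjusted p = 6.3e-14 and 4.4e-13, adjusted p = 0.47 and 0.55 with an estimated correlation). SRF and YAP targets (0.34 and 0.19, camera adjusted p = 7.1e-06 and 0.00069), immediate early genes (0.36 and 0.38, 0.012 and 0.0019), ERK feedback genes (0.59 and 0.42, 0.00081 and 0.034), sterol genes (0.38 and 0.5, 0.0082 and 0.0016), ribosome biogenesis (0.34 and 0.26, 0.00014 and 0.00016) and unfolded protein response (0.28 each, 0.0046 and 0.0022) were higher. Adjusted over the list alone 9 and 4 SRF and YAP targets, 1 and 2 immediate early genes, 2 and 0 ERK genes and 1 and 0 unfolded protein response genes were higher, and none of the sterol and ribosome lists. Their adjusted p with an estimated correlation were 0.12 and 0.2, 0.47 and 0.48, 0.47 and 0.69, 0.74 and 0.69, 0.59 and 0.62, and 0.47 and 0.59. Fatty acid oxidation (−0.44 and −0.33, 5.5e-06 and 0.00069), calcium handling (−0.51 and −0.34, 5.4e-05 and 0.00016) and oxidative phosphorylation (−0.21 and −0.24, 0.0014 and 0.00016) were lower, with adjusted p of 0.47 and 0.62, 0.47 and 0.59, and 0.68 and 0.62 with an estimated correlation. Of these 5 and 4 fatty acid oxidation genes, 5 and 6 calcium handling genes and none of oxidative phosphorylation were lower adjusted over the list alone. Secreted factors (0.41, 0.013) and extracellular matrix (0.11, 0.042, 0.26 with the block) were called with ET-1, and cAMP and CREB targets (0.42, 0.0018) with PE, at adjusted p = 0.41, 0.82 and 0.2 with an estimated correlation. With the block interferon genes (−0.3 and −0.22, 0.14 to 0.0071 and 0.16 to 0.011) and mitochondrial genes (−0.22 and −0.31, 0.28 to 0.009 and 0.058 to 0.00017) were lower and, with PE, secreted factors (0.3, 0.18 to 0.033) and heat shock genes (0.26, 0.08 to 0.033) higher. With an estimated correlation their adjusted p were 0.53 each for interferon, 0.55 and 0.46 for mitochondrial genes, 0.46 for secreted factors and 0.47 for heat shock. On the values as deposited cAMP targets (0.14 to 0.023) and heat shock (0.13 to 0.03) were called with ET-1, and sarcomere (0.19 to 0.043), extracellular matrix (0.1 to 0.017), secreted factors (0.03), NF-kB (0.11 to 0.029), mitochondrial genes (0.0053) and heat shock (0.016) with PE. In fits without the replicate block, leaving out either library of vehicle with JQ1 lost every call of a single gene. Fits that also used the block kept calls, in the ranges given further below.

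Whether JQ1 acted differently depending on the agonist was tested as a difference of JQ1 effects. Limma called 0 genes for ET-1 minus vehicle, PE minus vehicle and PE minus ET-1, while 616, 717 and 117 had an unadjusted p under 0.05. Limma-voom called 1, 2 and 1, plain variance moderation 1, 4 and 1, and the fit with the replicate block 5, 10 and 1. Of the latter 1, 2 and 1 were listed at 0 in the agonist group both without and with JQ1, where no JQ1 effect can be measured. The differences of Nppb were −0.44 ± 0.79, −0.88 ± 0.79 and −0.44 ± 0.79, and those of Hexim1 were 0.25, 0.09 and −0.15 ± 0.2, none called. For PE minus vehicle the Nppb difference was −0.89 in replicate 1 and −0.87 in replicate 2. Its SE with the block was 0.27, and it was not called there either (limma adjusted p = 0.26). For PE minus ET-1 the replicates disagreed, with 0.1 and −0.98. Leaving out ET-1 replicate 2 or replicate 1 of ET-1 with JQ1 gave 1 gene for ET-1 minus vehicle. For PE minus vehicle, leaving out PE replicate 2 gave 1 and replicate 1 of PE with JQ1 gave 2. For PE minus ET-1, leaving out ET-1 replicate 1, PE replicate 2 or replicate 1 of ET-1 with JQ1 gave 1, and replicate 1 of PE with JQ1 gave 2. Camera called 7, 5 and 4 lists, and none with an estimated correlation (adjusted p = 0.22 to 0.98, 0.79 to 0.95 and 0.4 to 0.99). Over all 11 comparisons fry called 39 of 308 list results, 29 of them also called by camera, and 0 for these differences.

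**Figure D3:**
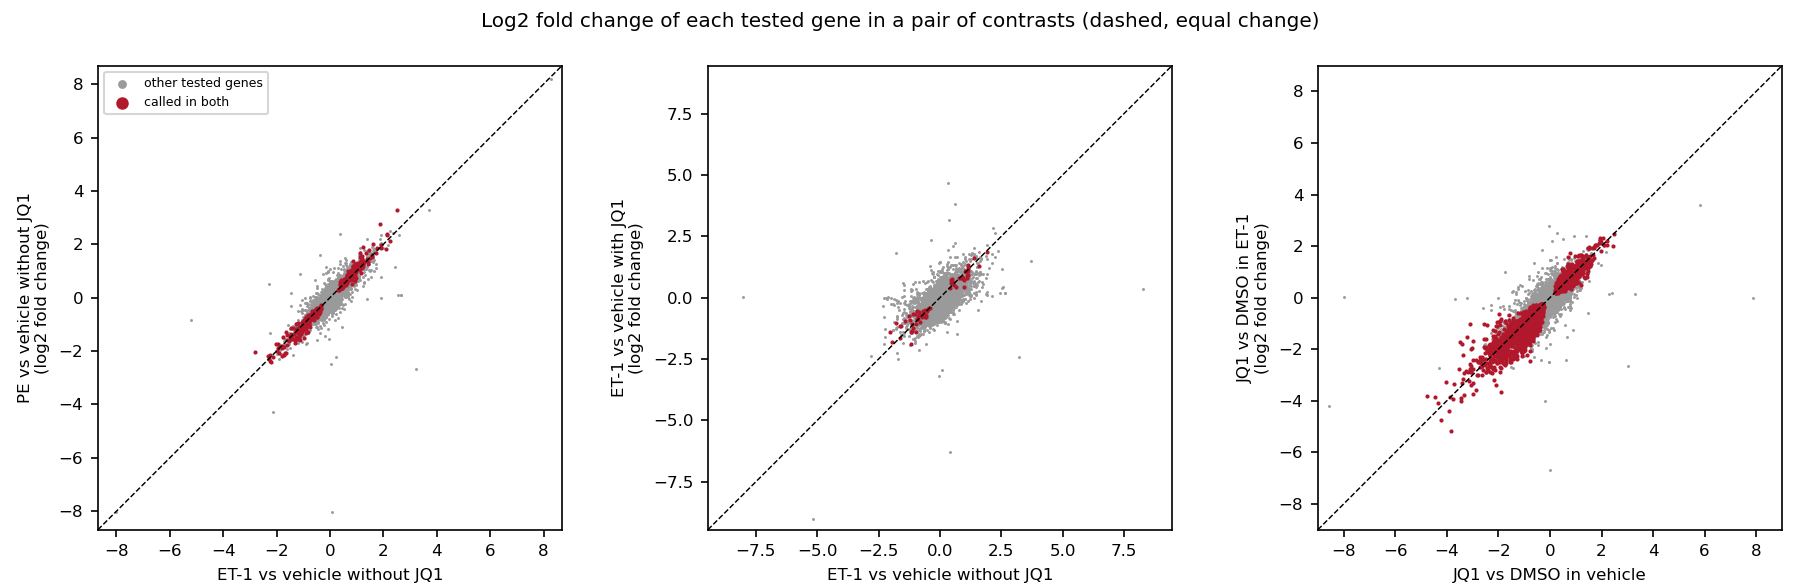
Log2 differences of 13793 genes in pairs of comparisons (ET-1 and PE against vehicle without JQ1; ET-1 against vehicle without and with JQ1; JQ1 against DMSO in vehicle and in ET-1), with each point a gene, red points called in both and the dashed line equal change. The correlations were 0.89, 0.64 and 0.88, and the slope of ET-1 with JQ1 on ET-1 without it, which noise lowers, was 0.6.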

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

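The genes and lists given first came from tests of the difference between JQ1 effects, which were planned, as was the replicate block under which the single genes passed. Of the 3 patterns weighed after them, the histones came from PE against ET-1 and the non-myocyte markers from JQ1 against DMSO. Of the tests of explanations below, all but the shift of short transcripts and the share of non-myocytes in 5 genes were chosen only after the result was seen, and so was the demand that both replicates bear out the shift of short transcripts.

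With the replicate block, the JQ1 effect in ET-1 minus that in vehicle was called for 5 genes, none of which passed without the block. Myh3, embryonic myosin, differed by 3.2 ± 0.24 (limma adjusted p = 0.014, 0.29 without the block): its level was 5.53 in vehicle and 0.151 in vehicle with JQ1, but 8.77 and 9.18 in ET-1. The mitotic gene Cdca8 differed by −0.97 (adjusted p = 0.026, 0.2 without the block), Ube2t by −0.9 (0.038, 0.2) and Fbxo5 by −0.93 (0.038, 0.29). Sct differed by 2 (0.038, 0.29), being at 1.51 in vehicle and listed at 0 in the other 5 groups, so its value restates the fall in vehicle and shows no JQ1 effect in ET-1, and a listed 0 may be a dropout of the quantification, which was not tested (0.29 without the block). Without vehicle replicate 1, ET-1 replicate 1, or either library of vehicle with JQ1 the blocked count was 0. Without replicate 1 or 2 of ET-1 with JQ1 or vehicle replicate 2 the genes called were in part others than these 5. Without ET-1 replicate 2 all of them were others.

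For the JQ1 effect in PE minus that in vehicle 10 genes were called with the block, of which 9 are named. Myh3 differed by 2.87 (adjusted p = 0.016, 0.51 without the block), Sct by 2 (0.03, 0.39), Ptgds by 1.39 (0.035, 1) and the placeholder AABR07034673.1 by 2.5 (0.0061, 0.064). Sct and the placeholder were listed at 0 in PE both without and with JQ1, so their values restate levels without JQ1. Wfdc1, which rose with PE and was at 0.106 with PE and JQ1, differed by −2.57 (0.035, 0.16), a value that nearly restates its rise of 2.76 with PE, since it lay at 0.0248 to 0.106 in all groups with JQ1. Ift43 differed by −1.09 (0.027, 0.74), Nxnl2 by −0.83 (0.035, 0.97), Ccdc107 by −0.98 (0.041, 1) and the family copy RF00017 by −2.43 (0.038, 0.74). Leaving out PE replicate 1, replicate 2 of PE with JQ1 or either library of vehicle with JQ1 lost every call. Without vehicle replicate 1, PE replicate 2 or replicate 1 of PE with JQ1 the genes called were in part others than the 10. Without vehicle replicate 2 the fewer genes called were all among the 10. For PE minus ET-1 only AABR07034673.1 was called, at 2.54 (0.0053, 0.056), which restates its call in PE against ET-1, since it was listed at 0 in PE without and with JQ1. That call was lost without PE replicate 1, ET-1 replicate 1 or replicate 2 of PE with JQ1. It held without each other library, beside calls of other genes.

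Gene lists differed in the size of the JQ1 effect, each called by camera at the preset correlation and none with an estimated one. In ET-1 relative to vehicle, cell cycle genes had a median difference of −0.78 with 0 of 28 positive and 24 lower adjusted over the list alone (camera adjusted p = 3.8e-37, adjusted p = 0.22 with an estimated correlation). Histones were at −0.57 (4.7e-17, 0.64 estimated), sterol genes at −0.57 (2.7e-05, 0.98), oxidative phosphorylation at −0.27 (6e-07, 0.98) and glycolysis at −0.19 (0.023, 0.98). Unfolded protein response genes were at 0.57 with 19 of 19 positive (0.00014, 0.73), and P-TEFb and BET genes at 0.1 (0.024, 0.64, and 0.051 on the values as deposited). In PE relative to vehicle, cell cycle genes were at −0.55 with 2 lower adjusted over the list alone (5.3e-18, 0.79 estimated), sterol genes at −0.47 (0.00013, 0.95), oxidative phosphorylation at −0.29 (7.2e-08, 0.95), unfolded protein response at 0.33 (0.035, 0.95) and P-TEFb and BET genes at 0.12 (0.032, 0.79). In PE relative to ET-1, histones were at 0.39 (1.1e-18, 0.59 estimated), cell cycle at 0.26 (5.2e-13, 0.59), SRF and YAP targets at −0.21 (0.0019, 0.4) and ERK feedback genes at −0.25 (0.0039, 0.99).

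With the block further lists were called. In ET-1 relative to vehicle these were extracellular matrix (0.22, adjusted p 0.59 to 0.0016), mitochondrial genes (0.23, 0.48 to 0.015) and fibroblast markers (0.24, 0.91 to 0.019), at adjusted p = 0.78, 0.79 and 0.78 with an estimated correlation. In PE relative to vehicle they were immediate early genes (−0.21, 0.14 to 0.045), ERK feedback (−0.13, 0.064 to 0.012, and 0.034 on the values as deposited), extracellular matrix (0.21, 0.82 to 0.014), mitochondrial genes (0.22, 0.38 to 0.012), fibroblast markers (0.25, 0.89 to 0.012) and histones (−0.18, 0.058 to 0.045), at adjusted p = 0.87 for histones and 0.69 for each other list with an estimated correlation. On the values as deposited secreted factors (−0.15, 0.16 to 0.029) and unfolded protein response (−0.14, 0.16 to 0.041) were called in PE relative to ET-1.

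The larger fall of cell cycle transcripts with JQ1 in ET-1 than in vehicle was weighed first. A smaller share of non-myocytes with JQ1 in ET-1 would have lowered their markers too, but the median difference of 37 markers was 0.14 (quartiles 0.02 and 0.26). That argues against it as the whole cause, as far as marker transcripts follow the share of these cells, which was not measured. Scaling was excluded as the cause, since the median was −0.73 or lower under the other scalings, and so was one library alone, since it stayed at −0.65 or lower with the block, and at −0.63 or lower without it, when each of the 8 was left out. Stronger loss of proliferation under JQ1 in the presence of ET-1 might be the biological explanation, but it was not tested, and the list was not called with an estimated correlation (adjusted p = 0.22).

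The lower histone transcripts with PE than with ET-1 were weighed next. For a shift of short transcripts across whole libraries, 856 other genes of 300 to 700 nt had a median of −0.08 (quartiles −0.13 and −0.01). It was −0.15 in replicate 1 and −0.01 in replicate 2. The histone quartiles, −0.41 and −0.3, lay below those of the other genes, which argues against such a shift as the whole cause. By the bounds set for the test, which both replicates had to meet, these values cannot tell whether it was a part. Reads moved only among the 34 tested copies would leave their summed level unchanged, but it differed by −0.33 (−0.46 and −0.2 in the replicate pairs). The sum is of the same genes, so it restates their lower level. It cannot show reads moved to copies outside these 34, which stays open. Fewer cells in S phase with PE could account for it, but 11 S phase genes had a median of −0.26 with −0.09 in replicate 1 and −0.37 in replicate 2, which cannot tell.

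The lower markers of non-myocytes with JQ1 were weighed last. A smaller share of such cells could lower them all: of 5 genes that mark the difference between replicates, 100% were lower with JQ1 in vehicle, too few to tell. In a wider set of 158 such genes, 89.2% were lower (87.3% and 86.7% in the replicate pairs) against 49% of all tested genes, which fits that explanation without proving it, and only 4 of them were called (111 lower and 9 higher with the block). Lower transcript output in unchanged numbers of these cells could give the same picture, and the medians of the 4 marker lists, within 0.24 of each other, cannot tell. No cell counts were used here, so both explanations may hold at these values of 89.2% and 0.24.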

How the results depend on the processing

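No call of a named gene changed direction under any alternative. Correlations between comparisons kept their size in fits of all libraries: 0.89 to 0.9 for ET-1 and PE (0.53 when taken from different replicates, which are single libraries and share none), and 0.88 to 0.89, 0.82 to 0.84 and 0.92 to 0.93 for JQ1 between vehicle and ET-1, vehicle and PE, and ET-1 and PE. Of 1384 results of named genes, 1295 stayed on their side of the threshold on the values as deposited (74 weaker, 15 stronger), 1302 under quantile normalization, 1353 with limma-voom, 1338 without a filter and 1206 with only the libraries compared (172 weaker). Leaving out 1 library at a time left 6281 results on their side, with 649 weaker and 26 stronger. With the replicate block 1067 stayed and 317 became stronger. Besides these 317, the counts and the 47 lists given above (46 gained, 1 lost), the block changed no other call. Where alternatives below moved a count, the cause was not tested, except that fits to only the compared libraries or without a library hold fewer samples. A group left with 1 library was assumed to vary like the other groups. Blocked fits with a library left out, blocked list tests with an estimated correlation, genes picked with JQ1 and responses from different replicates were added after the data were seen, and list tests were not repeated with libraries left out. With 2 libraries a group, the median SE of 0.15 (0.22 for differences of JQ1 effects) limits what could be called, and levels near the filter of 1 rescaled FPKM are limited by depth.

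On the values as deposited 208 genes were called for ET-1 and 532 for PE without JQ1, and 25 and 31 with JQ1. With the block the counts were 2537, 3314, 1601 and 1664, for JQ1 7279 in vehicle, 7849 in ET-1 and 7782 in PE, and for differences of JQ1 effects (ET-1 minus vehicle, PE minus vehicle, PE minus ET-1) 5, 10 and 1. With only the compared libraries they were 0 for either agonist without and with JQ1, 2933, 2346 and 3124 for JQ1, and 1 for PE minus vehicle. Without a filter 8 genes were called for PE against ET-1, 83 and 38 for ET-1 and PE with JQ1, and 4, 5 and 4 for the differences. A mean of at least 5 gave 0 for PE against ET-1. For the differences limma-voom gave 1, 2 and 1, plain moderation 1, 4 and 1, and a pseudocount of 1 gave 2 for PE minus vehicle and 1 for PE minus ET-1. Agonist responses with JQ1 averaged 0.7 and −0.59 for rises and falls with ET-1 and 0.69 and −0.64 with PE. In genes picked with JQ1 they were 0.85, −0.83, 0.86 and −0.87. Whether picking with JQ1 alone accounts for these larger values was not tested. List tests with an estimated correlation gave 0 calls, also with the block.

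Leaving out 1 library gave 0 to 47 genes for ET-1, 3 to 144 for PE, 0 to 3 for PE against ET-1, 2583 to 2949, 3562 to 4300 and 3313 to 3694 for JQ1 in vehicle, ET-1 and PE, 0 to 1, 0 to 2 and 0 to 2 for the differences, and 0 to 280 and 0 to 3 for ET-1 and PE with JQ1. With the block as well, the ranges were 626 to 2393, 708 to 2678, 1 to 5, 5430 to 6284, 6148 to 6900, 5786 to 6288, 0 to 3, 0 to 9, 0 to 3, 110 to 1864 and 81 to 1114 in the same order.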

Other observations

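Ddit3, which encodes the stress factor CHOP, rose with JQ1 in ET-1 from 41.1 ± 16 to 113 ± 1.9 (1.5, limma adjusted p = 0.0047) and in PE by 1.42 (adjusted p = 0.0062). The mitochondrial chaperone Hspd1 fell by 0.58 in ET-1 (adjusted p = 0.0013), while Dnaja1, a cytosolic co-chaperone, rose by 0.64 in vehicle (0.0018) and 0.66 in ET-1 (0.0011). The chemokine Ccl20 fell with JQ1 by 2.02, 2.48 and 2.34 on the log2 scale in vehicle, ET-1 and PE (0.0037, 0.0011 and 0.0015), and Spry1, an inhibitor of ERK signalling, by 1.2 in ET-1 (0.005) and 1.45 in PE (0.0023). Mllt3, a subunit of the super elongation complex, rose with JQ1 in ET-1 (0.91, 0.00087) and PE (1.02, 6e-04). Prkd1, a kinase downstream of both receptors, rose with JQ1 by 0.89 in vehicle (0.0019) and 0.79 in ET-1 (0.0025). Treatments are given where the naming rule picked the gene. For none of the genes in this paragraph was a difference between JQ1 effects called, without or with the block. A missing call does not show that the effects were alike. A treatment left out therefore neither marks nor excludes a change particular to the others.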
